A study of Drosophila melanogaster with 3 samples.

How the data were processed

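ChIP-seq peak lists of 3 biological replicates were used, all from whole embryos of 0 to 16 h that express HLHm7 with a C-terminal GFP, precipitated with an anti-GFP antibody. Per the labels, chromatin was sonicated and the size range was 200 to 800 bp. The replicate numbers are those of the labels, and the 3 samples form 1 group.

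Peaks were called by the authors for each replicate against a control, and for the 3 replicates pooled. Per the deposited descriptions of the files, every dm6 list was made against the same control alignment. The optimal set was derived from these lists by IDR, per the deposited descriptions. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here, and the control reads were not analysed here. The deposited lists are in narrowPeak format, on dm3 and on dm6. The deposited signal of a region is the authors' own value, with no stated scale, so it was compared only as a rank within a list. The deposited q-value of a region is given as −log10 and ran from 1.83 to 3.32 in the optimal dm6 set, and the p-value column is filled with a placeholder. The deposited summit position, given as another column, is an offset from the start of the region. The 2397 optimal dm6 peaks were checked to be the 2397 highest-signal regions of the pooled list, 7.99% of it, and the 2266 optimal dm3 peaks the 2266 highest of theirs. No read numbers are given, so depth per sample is unknown. No 2 replicate lists held the same values. The replicate lists on dm6 end at 30000 regions each and hold background regions too, per the file labels, so the comparisons rest on the optimal set and on each replicate's strongest regions.

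Peaks were placed on the dm6 gene models of Ensembl release 115 and on the matching RefSeq genome sequence, after a check that every peak ended within its chromosome arm. Analyses covered the arms 2L, 2R, 3L, 3R, 4 and X and 13945 protein-coding genes. Of the symbols listed in advance, 2 had no match in the annotation. No coordinates were converted between builds, and dm3 lists gave only numbers of regions and shares per arm. Software was Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

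Regions of different lists were counted as shared when their summits lay within 200 bp. Each replicate's list was reduced to as many top regions as there were optimal peaks, and chance was measured with 100 circular shifts. Summits were classed as promoter-proximal within 500 bp of a TSS, and otherwise by untranslated region, coding exon, intron or intergenic sequence. Location was compared with 100000 random positions by Fisher's exact test, and arms by binomial tests against their length. A gene was bound if a summit lay in its span or within 2 kb upstream, and each of 20 gene lists was compared with all other genes by a two-sided Fisher's exact test. The lists were also set against 10000 random lists matched on gene length in 20 bins. Each of 13 motifs was counted on both strands in windows of 201 bp at the summit and in flanks at 750 bp, without flanks that lay within 300 bp of another summit, with the reversed sequence as control; the GAGA repeat reads the same reversed and had none. E(spl)-C with 10 kb flanks was compared with 10000 random windows of the same arm. Adjusted p-values are Benjamini-Hochberg values within each of these families, with a threshold of 0.05. The list test was tested on simulated data with 200 genes of a 13945-gene table. Summits were placed evenly within gene spans, and genes of the preferred lists were hit 4 times as often per bp. The test called 20 of 20 such lists and 1 of 20 unchanged lists. All of the 20 gene lists hold fewer than 200 genes, so this does not show the power of the test for them.

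The design, the lists, the motifs and the alternatives were fixed before the data were examined, except that strong and weak peaks were also compared without the share found in every replicate, an alternative chosen after seeing the data. The genes named are the nearest-TSS genes of the 25 highest-signal peaks found in all 3 replicates, every gene of E(spl)-C from E(spl)mdelta-HLH to gro, and up to 4 bound members with the highest signal from each list, with the tagged gene first and with members that have no peak where this is said. Alternatives were a summit distance of 50 bp or any overlap of 1 bp, longer or shorter ranked lists, a promoter window of 1 kb, assignment by TSS, length-matched lists, motif windows of 101 bp, GC-matched background windows in bins of 2 percentage points, the upper part of the peaks by signal, and leaving out each replicate. A peak set without a replicate holds the optimal peaks with a top region in both of the others, from 1591 to 1665 of the 2397. The peaks themselves were still called with all 3 replicates. For a test of GC content added after the results were seen, flanks were weighted to the GC content of the summits in the same bins, with an interval from resampled peaks.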

Results

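Binding of HLHm7 was mapped in whole Drosophila melanogaster embryos of both sexes, collected from 0 to 16 h of age. HLHm7, the product of E(spl)m7-HLH, is a basic helix-loop-helix-orange repressor of the Enhancer of split complex, E(spl)-C, a gene cluster that Notch signalling switches on and whose products repress proneural genes. The embryos came from a transgenic line that stably expresses HLHm7 with GFP fused to its C-terminus, and chromatin was precipitated with an antibody against GFP (chromatin immunoprecipitation followed by sequencing, ChIP-seq). The 3 libraries are biological replicates of a single group, so no groups were compared: the comparisons are between replicates, and between bound and unbound parts of the genome. On the dm6 genome build the authors' optimal set, the peaks that passed their test of reproducibility (irreproducible discovery rate, IDR), held 2397 peaks with a median width of 384 bp. On the older dm3 build the same libraries gave 2266 peaks. The ranked lists behind the dm6 set held 30000 regions for each replicate and 30000 for the pooled replicates. Depth is unknown, because the peak lists carry no read numbers. Signal is the peak's own value as the authors' caller gave it and was used only to rank, filter or describe peaks within a list. Peaks and genes are not independent replicates, and the 95% Wilson intervals given for shares cover counting error only.

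The strongest peaks lay near genes of several unrelated kinds, and none of the 25 highest-signal peaks found in all 3 replicates belonged to a gene of E(spl)-C. The highest signal, 1743, was at -86 bp from the transcription start site (TSS) of CG14100 (FBgn0036889; 3L, 19590442 to 19590793, dm6), and this peak ranked 1 in each replicate. The next peak, with a signal of 1506, lay in an intron of ush, which encodes a partner protein of GATA factors with a role in blood cells, and its nearest TSS was that of cbt, which encodes a zinc finger transcription factor (2L, 480907 to 481272). It was followed by peaks at px, a gene of wing vein patterning (1426), Ugalt, a UDP-galactose transporter (1398), hll (1361), and ph-p, which encodes a Polycomb group protein (1285; X, 2137200 to 2137518). The summits at Ugalt and ph-p were at -31 and -492 bp from the TSS, whereas the peak nearest to tara (1255) was intergenic at -3157 bp. Promoter peaks at mRpL41, a mitochondrial ribosomal protein gene (1216), at Chro, which encodes the chromatin protein Chromator (1200), and at PNPase (1165) followed. The other peaks of this set were nearest to Lk6, Art3, CG4004 (2 peaks), CG11050, CG13323, CenG1A, CG1888, CHMP2B, CG31145, cno, GstE13, CG5098, Cib2 and Shc, with signals from 825 to 1115. Of the 25 peaks, 15 were within 500 bp of a TSS, 5 were intergenic, 4 were intronic, and 1, nearest to Cib2, lay in a coding exon of otp.

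The replicates shared most of their strongest regions. When each replicate's list was reduced to its 2397 highest-signal regions, 70.9% of the regions were shared by replicates 1 and 2, 68.1% by replicates 1 and 3, and 70.2% by replicates 2 and 3, with summits within 200 bp counted as shared. The mean over the pairs was 69.7% ± 1.45 (SD over 3 pairs, which share libraries), and randomly shifted lists never shared more than 1.25%. Across the optimal peaks matched in both replicates of a pair, Spearman's rho of the signal ranks was 0.725 for replicates 1 and 2 (2358 peaks), 0.647 for replicates 1 and 3 (2346 peaks) and 0.648 for replicates 2 and 3 (2361 peaks). Of the 2397 optimal peaks, 1437 (59.9%, interval 58.0 to 61.9%) had a top region in all 3 replicates, 592 in 2 replicates, 351 in 1 replicate, and 17 in 0 replicates. Within the full lists of 30000 regions, 2335 optimal peaks (97.4%) had a region in every replicate. Replicate 2 held 84.1% of the optimal peaks in its top list (82.6 to 85.5%), replicate 1 held 80.4% (78.7 to 81.9%), and replicate 3 held 79.4% (77.7 to 81.0%). The shares depend on the distance allowed between summits: with 50 bp the mean pair shared 52.3% and 41.5% of the optimal peaks were in every top list.

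Peaks concentrated at promoters and were rare in exons. Of the 2397 summits, 1072 (44.7%, interval 42.7 to 46.7%) were within 500 bp of an annotated TSS, against 11.5% of random positions on the same arms, a 3.88-fold difference (odds ratio 6.20; the p-value of the two-sided Fisher's exact test was too small for the software to represent). Coding exons held 9 summits (0.376% against 13.3% of random positions, adjusted exact p = 3.42e-129), and 3' untranslated regions held 20 (0.834% against 5.16%, adjusted p = 5.90e-31). Intergenic sequence away from promoters held 365 summits (15.2% against 30.1%, adjusted exact p = 3.26e-62). Introns held 913 summits, 38.1% against 39.1% of random positions (adjusted exact p = 0.383). This value passed the threshold, as a lower share, when promoters were taken as 1 kb to either side of a TSS (30.9%, adjusted exact p = 1.73e-07) and when only peaks with a top region in both replicates 1 and 3 were used (36.1%, adjusted p = 0.0206). Promoters were assigned first, so their excess lowers the share left for every other class. Introns held 913 of the 1325 summits away from promoters. Promoters took 44.7% of summits but 11.5% of random positions, while introns held 38.1% and 39.1%. Away from promoters the intron share was therefore higher for summits than for random positions, a difference that was not tested. The 5' untranslated regions beyond the promoter window held 18 summits (0.751% against 0.805%, adjusted exact p = 0.908). The median distance to the nearest TSS was 697 bp for summits and 4209 bp for random positions. Of the 27603 pooled regions outside the optimal set, 19.7% were promoter-proximal. All p-values in this comparison are from Fisher's exact tests with Benjamini-Hochberg adjustment and measure counting error, not the spread between embryos.

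**Figure D1:**
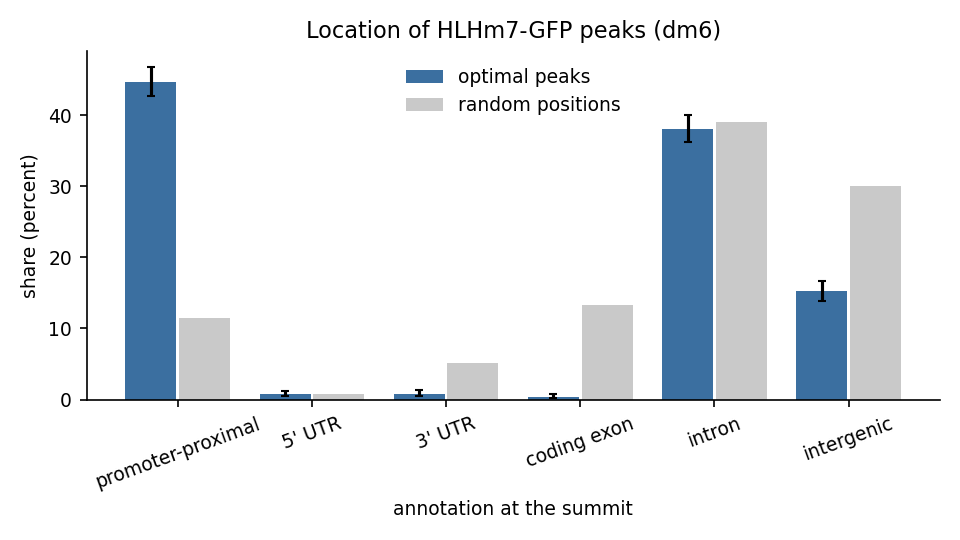
Share of the 2397 optimal dm6 peak summits (blue, with 95% Wilson intervals) and of 100000 random positions (grey) by annotation, in percent. The promoter-proximal share is 44.7% for summits and 11.5% for random positions, and coding exons hold 0.376% of the summits.

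Among the chromosome arms, chromosome 4, the small and largely heterochromatic arm, stood apart. It carried 4 peaks, 0.167% of all peaks (interval 0.0649 to 0.428%) against 1.01% of the sequence, or 2.97 peaks per Mb (two-sided binomial test, adjusted p = 6.04e-06). These peaks lay nearest to lgs, zfh2, Sox102F and fuss, named here because the count was low and chosen after the values were seen. Of the pooled regions outside the optimal set, 0.0978% lay on chromosome 4, so against these regions the optimal peaks were not rarer there. The X carried 456 peaks, 19.02% against 17.6% of the sequence (adjusted exact p = 0.204), and the arms 2L, 2R, 3L and 3R carried from 17.1 to 19.1 peaks per Mb without passing the test. Against other baselines the X stood higher. It held 13.35% of the pooled regions outside the optimal set, and 20.8 optimal peaks per 100 genes, against 5 to 17.9 on the other arms. The top lists of the replicates had from 17.9 to 18.3% of their regions on the X. These comparisons were not tested.

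At E(spl)-C itself, the tagged gene E(spl)m7-HLH carried a peak at -281 bp from its TSS (3R, 26036565 to 26036948, dm6). Its signal was 170, rank 860 of 2397, with ranks of 1438, 1140 and 507 in replicates 1, 2 and 3. The strongest peak of the complex was at gro, which encodes the corepressor Groucho that E(spl) proteins recruit. It lay inside the gene, at -131 bp from an annotated TSS (3R, 26042390 to 26042633), with a signal of 737 and rank 38, and a weaker peak lay at -38 bp from another TSS of gro (221, rank 524). Peaks were also found near E(spl)malpha-BFM, a Bearded family gene (178, rank 785), E(spl)m3-HLH (139, rank 1251) and E(spl)m6-BFM (107, rank 1847; 2046 bp downstream of the TSS and outside the assignment window). E(spl)mdelta-HLH, E(spl)mgamma-HLH, E(spl)mbeta-HLH, E(spl)m5-HLH, E(spl)m8-HLH, Kaz-m1, E(spl)m2-BFM and E(spl)m4-BFM had no assigned optimal peak. Together with peaks at Cmpk, RpL34a and Trmt61 in the 10 kb flanks, the 72.3 kb window held 9 peaks, or 125 per Mb, against 17.6 per Mb on 3R and a mean of 1.26 peaks in random windows of its length on the arm (percentile 99.9, two-sided permutation p = 0.0018). Without the flanks the count was 6 (permutation p = 0.0086). The RpL34a and Trmt61 peaks overlap, with summits at 26059283 and 26059514, and may mark the same site. The random windows overlap each other too, so both p-values are less exact than the number of windows implies. The line carries a transgene of this gene, and an extra copy of neighbouring sequence was not measured.

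**Figure D2:**
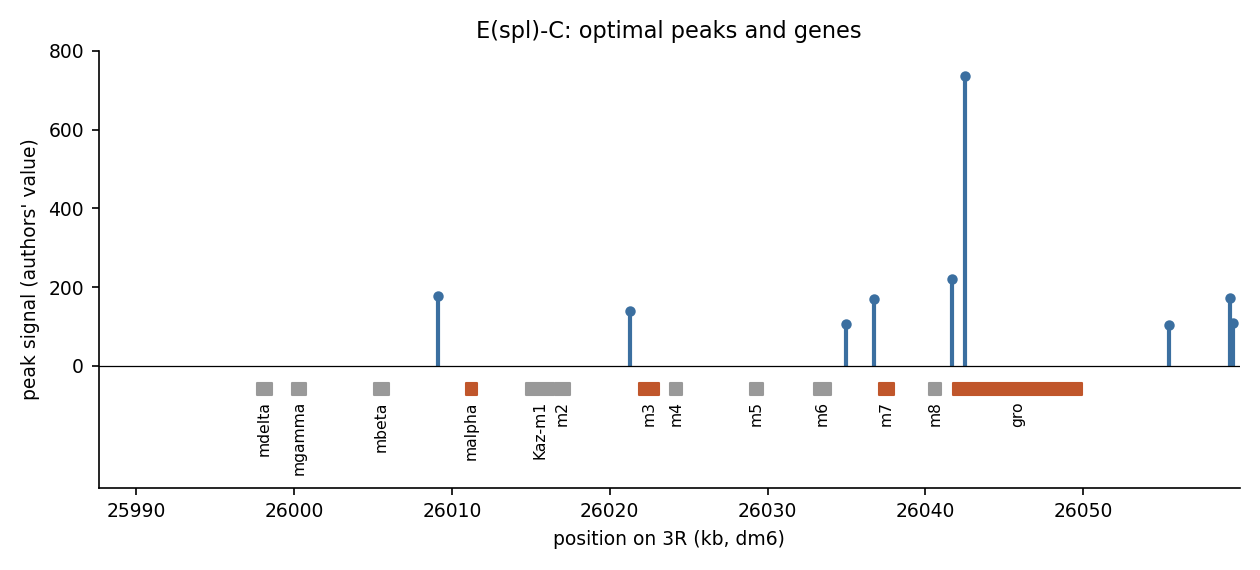
Optimal dm6 peaks in E(spl)-C with 10 kb flanks on 3R: each blue line stands at a summit and its height is the authors' peak signal. Boxes are the genes from E(spl)mdelta-HLH to gro with the E(spl) prefix left out, orange where a peak was assigned to the gene and grey otherwise; the highest peak, at gro, has a signal of 737.

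Across the genome, cytosolic ribosomal protein genes and highly transcribed housekeeping genes were bound more often than other genes, and chemoreceptor genes less often. A gene counted as bound with a summit in its span or up to 2 kb upstream, and 2387 of 13945 protein-coding genes (17.1%) were bound. Of the 92 ribosomal protein genes, 51 (55.4%) were bound, against 16.9% of the other genes (odds ratio 6.13, adjusted exact p = 1.53e-15). The strongest of them were RpS27 (signal 628, rank 51), RpL7 (558, rank 67), RpL32 (379, rank 147) and RpL23A (369, rank 162). Of 12 highly transcribed housekeeping genes, which include RpL32, 8 were bound (66.7%, adjusted exact p = 0.00125), among them the glycolytic gene Gapdh2 (348), the elongation factor gene eEF1alpha1 (332) and the actin gene Act5C (285). The eEF1alpha1 peak lay in an intron of ERp60, whose TSS was nearest. The housekeeping share was 50% without replicate 2 or 3 and 41.7% without replicate 1 (adjusted exact p = 0.0412 for the last). Sets without a replicate hold 1591 to 1665 of the 2397 peaks, which can lower the share of any list. Both lists also passed against random genes of the same lengths, which were bound at 11.4% for the ribosomal proteins (adjusted permutation p = 0.002, from the smallest p that 10000 draws can give) and 16.4% for the housekeeping genes (adjusted p = 0.00533). Chemoreceptor genes, which act in sense organs, were bound less often: 2 of 179 (1.12%, adjusted exact p = 3.28e-11), namely Or88a (144) and Or9a (107), whose peaks were at promoters of the neighbouring genes CG12402 and Neb-cGP. With any replicate left out the share was 0.559%, from 1 gene. Bound genes were longer, with a median of 4330 bp against 1961 bp for the rest.

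Of the developmental lists, the EGFR, Notch and mesoderm lists passed the test against other genes and did not pass against genes of the same lengths. In the EGFR pathway list 7 of 12 genes were bound (58.3%, adjusted exact p = 0.00757), including the ligand-processing gene S (508, rank 78), the inhibitor aos (392, rank 137) and the ligands spi (379) and vn (338). In the Notch pathway list 9 of 21 were bound (42.9%, adjusted exact p = 0.0203), with gro first, then the receptor gene N (255, rank 388), rumi, an O-glucosyltransferase gene (249), and aph-1, a gamma-secretase gene (231). Delta, Ser and Su(H) had no peak. In the mesoderm and muscle list 7 of 15 were bound (46.7%, adjusted exact p = 0.0255), with Mef2, the muscle differentiation factor, first (685, rank 42), then zfh1 (262), nau (159) and how (123). The Mef2 peak was at -171 bp from the TSS of Pdrg1, inside Pal1, and was counted because it lay in the 2 kb upstream of Mef2. These genes are long. Random genes of the same lengths were bound at 34.7% for the EGFR, 26.1% for the Notch and 28.9% for the mesoderm list, and the lists lay above these means without passing (adjusted permutation p = 0.529 for each). With a summit within 1 kb of a TSS required, the Notch list was bound at 28.6% against 12.4% of other genes (adjusted exact p = 0.188), the EGFR list at 16.7% and the mesoderm list at 13.3% (adjusted p of 1 for both). The mesoderm share was 33.3%, 26.7% and 20% without replicates 1, 2 and 3, and did not pass in any of these sets (adjusted exact p from 0.0952 to 0.768), which hold fewer peaks.

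The remaining lists did not pass the test against other genes. None of the 11 proneural and neural bHLH activators, among them ac, sc, ase, ato and da, was bound (0 of 11, adjusted exact p = 0.418), a count that at this list size cannot show a deficit. Of the E(spl)-C bHLH repressors 2 of 7 were bound (adjusted exact p = 0.572), and of the Bearded family 1 of 8. In the list of Hairy-related repressors outside the complex 1 of 7 was bound, the clock repressor gene cwo (208). That list also holds run and emc, which are not Hairy-related repressors and had no peak. The Bearded and Hairy-related lists each had an adjusted exact p of 1. Of the neuroectoderm and neuroblast regulators 4 of 23 were bound (adjusted exact p = 1), including brat (310) and grh (128). Of the glial genes 3 of 8 were bound, with moody (298) and pnt (174) first (adjusted exact p = 0.329). Of the endoderm and hindgut regulators 3 of 10 were bound, with fkh (338) and bowl (206) first (adjusted exact p = 0.600). In the list of tracheal and epidermal regulators 3 of 9 were bound (adjusted exact p = 0.378). The first was sim (415), which is known as a regulator of the central nervous system midline, followed by bnl (109) and sty (99.1). Of the segmentation and signalling genes 6 of 19 were bound, with dpp (268) and brk (189) first (adjusted exact p = 0.329). This list passed, as a higher share, when each peak was given to the gene with the nearest TSS (adjusted exact p = 0.0299). Its share was 10.5% when any replicate was left out and 5.26% with a summit within 1 kb of a TSS required (adjusted exact p = 1 in each case). Among the other lists of this paragraph, the tracheal and epidermal share fell from 33.3% to 11.1% without replicate 1 or 2, and the neuroectoderm share from 17.4% to 8.70% when any replicate was left out. The share of E(spl)-C bHLH repressors fell from 28.6% to 14.3% without replicate 1 or 3, the glial share from 37.5% to 25% without replicate 2 or 3, and the bound germ cell genes to 0 without replicate 1 or 2. The sets without a replicate hold fewer peaks, 1591 to 1665 of 2397, so such falls do not by themselves show dependence on a replicate. A single member was bound among 9 hemocyte genes (ush), 8 germ cell genes (nanos, through a peak at the promoter of CG11779), 8 Hox genes (Antp) and 11 cell cycle genes (trbl), each list with an adjusted exact p of 1. Of the 14 chorion and vitelline membrane genes, which are active in the ovary, 0 were bound (adjusted exact p = 0.329).

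**Figure D3:**
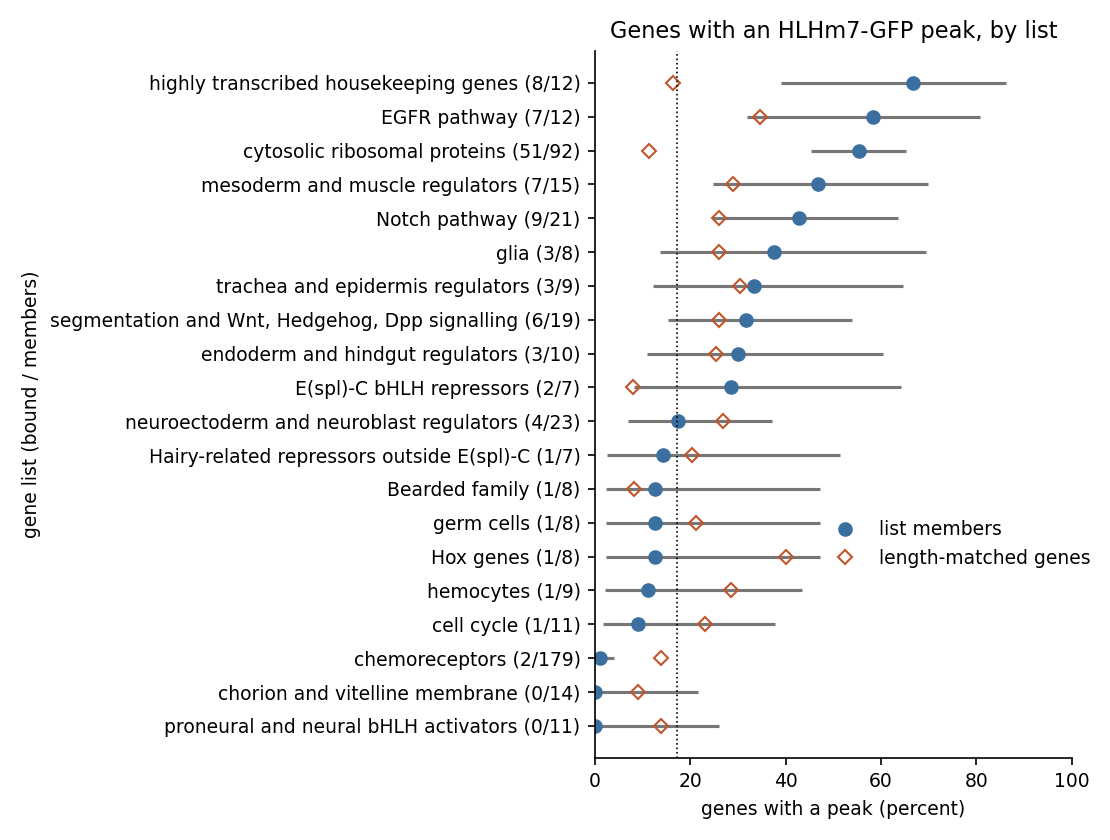
Share of each gene list with an optimal peak in the gene span or up to 2 kb upstream, in percent (blue points with 95% Wilson intervals). Orange diamonds are means of random genes matched on length and the dotted line is the share of all genes, 17.1%; ribosomal protein (55.4%) and housekeeping genes (66.7%) lie above both.

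At the summits the promoter elements DRE and Motif 1 were more frequent than in the flanks, and the class C site, the E-box CACCTG and the Zelda site were rarer. The DNA replication-related element, DRE (TATCGATA), which is common in housekeeping promoters, lay within 100 bp of 3.38% of summits and in 0.433% of flank windows centred 750 bp away (7.81-fold, adjusted exact p = 1.88e-20). This was 5.12-fold without replicate 1 and 14.6-fold with windows of 50 bp to each side. The Motif 1 core (GGTCACACT), another element of such promoters, was at 1.33% against 0.368% (3.63-fold, adjusted exact p = 4.94e-05). Of the 81 summits with DRE, 80 were promoter-proximal, as were 29 of the 32 with Motif 1. Flanks lie 750 bp away, so location at promoters may account for both excesses, and unbound promoters at large were not compared. The class C site CACGCG was listed in advance as a site of Hairy and E(spl) proteins, and the preference of HLHm7 itself was not measured. It was at 77 of 2397 summits, 3.21% (interval 2.58 to 3.996%) against 4.89% of flanks (0.657-fold, adjusted exact p = 0.00325). The E-box CACCTG (6.09% against 9.22%, adjusted exact p = 2.61e-05) and the Zelda site (0.709% against 1.39%, adjusted p = 0.0334) were also rarer at summits. Summit windows held 38.1% GC and flanks 42.9%, and against random windows of the same GC content class C was at 1.23-fold (adjusted exact p = 0.200), CACCTG at 1.11-fold (adjusted p = 0.331) and the Zelda site at 0.773-fold (adjusted p = 0.424), so none of these deficits passed there. The class C deficit also missed the threshold without replicate 3 (0.701-fold, adjusted exact p = 0.0589) and with the 1198 strongest peaks (0.746-fold, 0.189), as did the Zelda deficit (0.611-fold, 0.232, and 0.414-fold, 0.0766, against 0.512-fold over all peaks). The Zelda deficit missed it as well without replicate 2 (0.512-fold, adjusted exact p = 0.0573) and with windows of 50 bp to each side (0.89-fold, 0.864). Motif 1 did not pass with the strongest peaks (2.39-fold, 0.189). Reversed sequences were used as a control of base composition, but some do not measure composition alone. GTGCAC, the reverse of CACGTG, lies inside CAGTGCAC, a word itself more frequent at summits away from promoters than in flanks. The reversed class C sequence was at 7.68% of summits and 7.27% of flanks (1.06-fold, adjusted exact p = 0.662), and at 2.02-fold against the GC-matched windows. Other reversed sequences did differ from the flanks: the reverse of CACATG was at 11.35% against 6.23% (adjusted exact p = 3.73e-12) and that of CACGTG at 8.09% against 4.22% (3.81e-10). The reverses of CACCTG (4.09% against 6.99%, adjusted exact p = 2.40e-06), of the N-box (20.3% against 25.5%, 3.60e-06) and of the Grainy head site (3.50% against 6.30%, 1.81e-06) were rarer at summits. The class B E-box CACGTG (1.19-fold, adjusted exact p = 0.341), the N-box (0.978-fold, 0.649), the E-boxes CAGCTG (1.18-fold, 0.0557), CATATG (1.21-fold, 0.0557) and CACATG (0.842-fold, 0.0557), and the Su(H) site (0.813-fold, 0.341) did not pass against flanks. Neither did the GAGA repeat (1.08-fold, 0.607) and the Grainy head site (0.617-fold, 0.132). Some of these passed with other settings: CATATG without replicate 2 (adjusted exact p = 0.0378) and with windows of 50 bp to each side (0.0479), CACATG without replicate 1 (0.766-fold, 0.0249) and without replicate 2 (0.746-fold, 0.00947), and the Su(H) site without replicate 2 (0.591-fold, 0.0378). The direction changed for CAGCTG without replicate 1 (0.960-fold) and for the GAGA repeat without replicate 1 (0.997-fold), without replicate 2 (0.961-fold), with the 1198 strongest peaks (0.967-fold) and with windows of 50 bp to each side (0.718-fold). Against GC-matched windows CACGTG (1.58-fold, adjusted exact p = 0.00411), CAGCTG (1.62-fold, 5.52e-10), CATATG (1.27-fold, 0.00809), the N-box (1.13-fold, 0.00996) and the GAGA repeat (2.04-fold, 6.61e-08, without a reversed control since it reads the same reversed) were higher, and DRE (4.56-fold) and Motif 1 (7.11-fold) were higher there too. The reverse of CACGTG was at 2.24-fold against those windows and the reverse of CAGCTG at 0.960-fold. The reversed Motif 1 was at 6.29-fold there (2.36-fold against flanks, adjusted exact p = 0.110) and the reversed DRE at 1.07-fold.

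**Figure D4:**
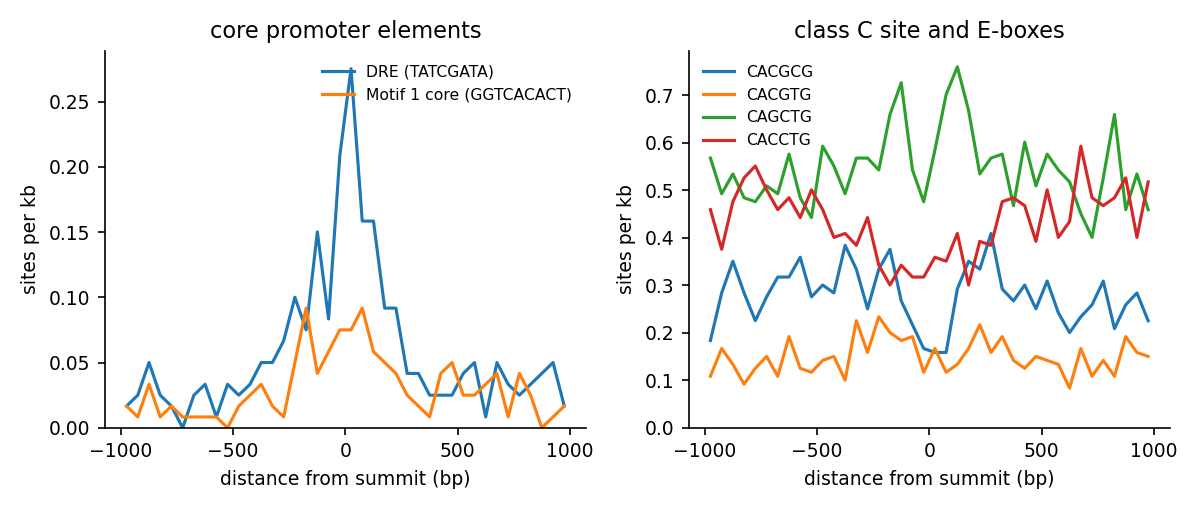
Sites per kb by distance from the summit in bp, over 2397 optimal peaks: DRE and Motif 1 on the left, the class C site CACGCG and the E-boxes CACGTG, CAGCTG and CACCTG on the right. DRE rises at the summit (present within 100 bp at 3.38% of peaks), whereas CACGCG is lowest near the summit and CACCTG is low over a broader stretch around it.

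Strong peaks were more often promoter-proximal than weak ones. Among the 479 highest-signal peaks 50.7% were within 500 bp of a TSS, against 40.7% of the 479 lowest (odds ratio 1.5, adjusted p = 0.0171, two-sided Fisher's exact tests of 15 features). When all peaks were split into 1198 strong and 1198 weak ones the difference was 3.84 percentage points and did not pass (adjusted exact p = 0.193). Of the 15 features, 1, the share found in every replicate, is set in part by the ranking on pooled signal, and is given without a test: 99.8% against 2.09%. With that feature left out of the adjustment, an alternative chosen after seeing the data, the promoter difference had an adjusted exact p = 0.0320. No motif passed the test between strong and weak peaks: the class C site was at 4.18% and 3.76% (adjusted exact p = 0.931), DRE at 2.51% and 3.76% (0.801), and CAGCTG at 7.31% and 11.9% (0.104).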

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

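The comparison with length-matched genes was planned, but its limits as a test of gene length were set after its value had been seen, and the tests of GC content and of an extra locus copy were chosen after the results they bear on had been seen.

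Weak regions on chromosome 4 in the replicate lists, and regions of the dm3 lists outside the main arms, were not part of a comparison in the report, and their counts exceed the 3 that a count of 0 allows. Replicate 3 had 260 regions on chromosome 4 among its 30000, against 35 and 30 in replicates 1 and 2. In the dm3 lists, regions outside the main arms numbered 175, 103 and 134 in replicates 1, 2 and 3, or 5.83, 3.43 and 5.13 per 1000 regions, since the dm3 list of replicate 3 held 26124 regions and the others 30000.

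Ribosomal protein genes carried peaks far more often than other genes. Gene length as the cause is argued against by the length-matched random genes, of which 11.4% were bound. Peaks at separate promoters of neighbouring genes are argued against as well, because 92.2% of the bound ribosomal protein genes own the TSS nearest to a peak. This cannot tell apart promoters that lie very close together. The overlapping peaks of RpL34a and Trmt61, for instance, have summits at -16 and 6 bp from the respective TSS. How many ribosomal protein promoters have such a neighbour was not counted. Unspecific recovery of active promoters stays open: a class C site lay within 100 bp of 21.3% of the summits at ribosomal protein promoters, but no control library was analysed here, and the sources used do not say whether the peak calls used input or a mock precipitation. Of biological explanations, only guidance of HLHm7 by class C sites was looked at, under the other observations, and it stays open.

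Class C sites were rarer at summits than in flanks. The lower GC content of summits may account for this: against flanks weighted to the same GC content the ratio was 1.05 (95% bootstrap interval 0.796 to 1.39), and the 59 other words of the same letters were at a median of 0.628-fold against flanks, from 0.319 to 1.10, with 33 of them as low as class C. The reversed sequence, at 1.06-fold, was among the 3 words that were not rarer at summits, so base composition does not set every word alike. Imprecise summits could also hide sites that lie beside them: 300 bp to each side the ratio to GC-matched windows was 1.64 (1.41 to 1.92), above that at the summit but with overlapping intervals (0.954 to 1.58 at the summit), and this stays open. No biological explanation was tested.

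E(spl)-C held more peaks than most windows of its arm. For the window with its 10 kb flanks, promoter density is argued against as the whole cause. Among windows with 27 TSSs, give or take 3, its count of 9 peaks was at percentile 99.3. That count includes peaks at Cmpk, RpL34a and Trmt61 in the flanks, and the RpL34a and Trmt61 peaks overlap. The complex without flanks, with 6 peaks, was not set against windows of a like number of TSSs, so promoter density there was not tested. These 3043 windows overlap each other, and the highest count among them was also 9, so the percentile is approximate. An extra copy of the locus carried by the transgene could raise all signal there, and weaker pooled regions, 29 in the window, were at percentile 79.9 of the same windows, which neither shows nor excludes such a copy. The 8 adjacent windows of the same length held from 7 to 21 weaker regions, and from 4 to 27 regions of a replicate against 43 to 48 at the complex, which goes with a copy, but they also held fewer TSSs, from 2 to 20. Binding of the repressor to its own complex stays open as a biological explanation that was not tested.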

How the results depend on the processing

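The alternatives were fixed before the data were examined, except the comparison of strong and weak peaks without the share found in every replicate, which was chosen after seeing the data. Of the 40 alternative values of the main results, 25 were counted as unchanged. For gene lists and motifs this compared only the number that passed, not which ones passed or in which direction. Numbers of 5 or 7 gene lists were counted as unchanged from 6, and 5, 6 or 7 motifs as unchanged from 5. The rest of the 25 kept their direction and side of the threshold or stayed within their spread. The values that changed are as follows, along with the GC-matched windows, which were among the 25. The mean share of regions that replicates had in common was 52.3% with summits within 50 bp, 75.5% with the top 1000 regions, and from 68.1 to 70.9% over single pairs. Optimal peaks in every top list were 41.5% with 50 bp, 84.0% with lists of double length, and from 66.4 to 69.5% when a replicate was left out, where fewer replicates are asked for. Of the 6 gene lists that passed, 3 passed with a summit within 1 kb of a TSS and 3 with length-matched lists, in each case the ribosomal protein, housekeeping and chemoreceptor lists. The number of motifs that passed, 5, was 2 with the 1198 strongest peaks, where fewer peaks are tested, and from 3 to 7 when a replicate was left out, the lowest without replicate 3; the cause was not tested. With GC-matched windows 7 motifs were higher and 0 lower, against 2 higher and 3 lower with flanks. The ratios of class C, CACCTG, the N-box and CACATG turned to 1.23, 1.11, 1.13 and 1.07. The GC-matched background differs from the flanks in place as well as in GC content. Of the 2 features that differed between strong and weak peaks, 1 did so between the upper and lower 1198; this is the share found in every replicate, which the ranking sets in part. Without it 1 of 14 differed, and 0 between the upper and lower 1198 (Fisher's exact tests, 3 at an unadjusted p under 0.05). Among the single lists, motifs, locations and features of strong and weak peaks, 225 values stayed on their side of the threshold, 20 lost and 12 gained a call, and 3 turned with a call in either setting. Of the 225, 37 changed direction without a call in either setting. Depth is unknown, so its limit on weak peaks was not measured. No paired analysis was possible because the samples form a single group.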

Other observations

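The tests of gene families and motifs here were chosen after the results on ribosomal proteins and summit sequences had been seen, as was the test of 8-mers; the limits for unbound ribosomal protein promoters were set before their values were known.

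Beyond the cytosolic ribosomal proteins, none of 5 further families of housekeeping genes passed the test against other genes, with a summit within 1 kb of a TSS counted and 12.4% of the rest bound. Of the mitochondrial ribosomal protein genes 10 of 73 were bound (13.7%, interval 7.61 to 23.4%, adjusted exact p = 0.721), with mRpL41 and mRpS10 first. Of the proteasome subunit genes 3 of 48 were bound (6.25%, adjusted exact p = 0.407), of the translation initiation factor genes 8 of 44 (18.2%, 0.407), of the tRNA synthetase genes 3 of 17 (17.6%, 0.517), and of the RNA polymerase II subunit genes 4 of 13 (30.8%, 0.151). Cuticular protein genes (1 of 70, 1.43%, adjusted exact p = 0.0108) and cytochrome P450 genes (2 of 85, 2.35%, 0.0108) were bound less often. Odorant-binding protein genes (1 of 51, adjusted exact p = 0.0523) and Osiris genes (1 of 25, 0.458) did not pass. The p-values are from two-sided Fisher's exact tests of 9 families.

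Promoter and distal peaks carried different sequences. DRE lay within 100 bp of 80 of 1072 promoter-proximal summits (7.46%) and of 1 of 1325 other summits (adjusted exact p = 1.24e-26), and Motif 1 at 2.71% and 0.226% (2.63e-07). CACGCG was at 4.94% and 1.81% (adjusted exact p = 6.45e-05) and CAGCTG at 14.3% and 7.25% (1.72e-07), whereas CATATG was at 5.597% and 9.81% (3.53e-04). At the 47 promoter peaks of ribosomal protein genes CACGCG was at 10 summits (21.3%, interval 11.99 to 34.9%), against 4.20% of the other 1025 promoter peaks (adjusted exact p = 3.05e-04). There CACGTG was at 12.8% against 3.32% (adjusted exact p = 0.0206), DRE at 29.8% against 6.44% (3.26e-05), and Motif 1 at 14.9% against 2.15% (6.43e-04).

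A hypothesis is that class C sites guide HLHm7 to part of the ribosomal protein promoters. Within 150 bp of a TSS, 15 of 51 bound ribosomal protein genes (29.4%) and 5 of 41 unbound ones (12.2%) had the site (two-sided Fisher's exact test, p = 0.0737, and 0.772 when adjusted over 13 motifs). DRE was within that distance at 31.4% of the bound and 26.8% of the unbound ones (exact p = 0.654). Motif 1 was at 15.7% and 4.88% (odds ratio 3.63, against 3 for class C, exact p = 0.176). CACGTG was at 31.4% and 19.5% (exact p = 0.237), so class C did not stand apart from these. The class C difference was not past the threshold, so ribosomal protein promoters that hold the site whether bound or not may account for the share, and the hypothesis stays open.

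Besides DRE, further words recurred at summits. The 10 8-mers most in excess over flanks at odd-ranked peaks were picked separately for promoter peaks and for other peaks. Of the promoter set 10 of 10 were enriched at even-ranked promoter peaks, and of the other set 6 of 10 at even-ranked peaks away from promoters. This argues against words picked by chance, although 8-mers over all peaks had been looked at before. In promoter peaks 3 of the 10 were DRE or shared 7 of its bases, and the other 7 included CAACACTG (4.75% against 0.570% of flanks, adjusted exact p = 2.12e-07). Away from promoters the most frequent was CACTGAGA, within 75 bp of 5.06% of the even-ranked summits against 0.595% of flanks (adjusted exact p = 1.99e-09), followed by TACACTGA (3.42% against 0.521%, 6.13e-06). AGATGGCG (2.83% against 0.744%, adjusted exact p = 0.00117) and CAGTGCAC (2.83% against 0.819%, 0.0015) came next. AGATGGCG is part of the sequence that the insulator protein CTCF recognises in flies. CACTGAGA and AGATGGCG were also more frequent than in flanks at promoter-proximal summits, at 1.40% against 0.0933% (adjusted exact p = 1.13e-05) and 1.77% against 0.793% (0.0388). No insulator protein data were analysed here.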
